A study of Drosophila melanogaster with 10 samples.

How the data were processed

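RNA sequencing was analysed from 10 libraries of Drosophila melanogaster S2 cells, a line derived from late embryos whose cells resemble blood cells (hemocytes). Per the labels and column names, cells were treated with double-stranded RNA to knock down (KD) a gene and were transfected with the proneural transcription factor Achaete (Ac) and its partner Daughterless (Da). Ac was wild type (WT) or the variant R29G. The knockdowns targeted the histone variant H2A.Z (gene His2Av), actin-related protein 6 (Arp6, a subunit of the complex that places H2A.Z into chromatin) or, as control, Luc. The libraries form 2 sets. Set 1 holds 2 libraries each of Luc KD with Ac WT, Luc KD with Ac R29G and H2A.Z KD with Ac WT. Set 2 holds 2 libraries each of Luc KD and Arp6 KD, all with Ac WT. Per the labels' protocols, libraries were made with an MGIEasy kit or a TruSeq mRNA kit; which library had which kit is not given in the sources used here.

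Library values came from 3 deposited tables. Table A and table B each held 1 library of every group of set 1, and table C held the 4 libraries of set 2. The columns of tables A and B carry no replicate number, and their Luc KD columns were assigned to the controls of set 1 because they share tables with R29G. The deposited values are a size-factor-scaled signal per gene, that is, read counts divided by 1 factor per library. Whole reads could be recovered from them, because 100% of the values were whole multiples of the smallest value in their column within a tolerance of 0.001 reads. The authors also deposited 2 tables of their own comparisons, which hold a mean signal, log2 fold changes with standard errors, a score (fold change over its standard error), p-values and adjusted p-values, with the column names of DESeq2, per the file headers. Adjusted p-values missing from the deposited table of H2A.Z KD (8012 features) were kept as missing. Those tables listed 70 features with a mean above 0 and no read in the 6 libraries of set 1, and 64 of these were not listed in set 2 either. The authors' fit therefore did not rest on these values alone. Whether other libraries or another count of the same libraries entered it is not known. The submitters' processing notes name Partek and the genome BDGP6, without a role. The aligner, the counter and whether counting used the strand are not given in the sources used here. Antisense genes and the genes they overlap therefore cannot be told apart, and genes with close paralogs are uncertain.

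Recovered depth was 33712374 and 26050325 reads for Luc KD with Ac WT of set 1 (tables A and B), 31544265 and 32052787 for Ac R29G and 29258719 and 24500413 for H2A.Z KD. In set 2 it was 9396318 and 9966586 for Luc KD and 10246872 and 10608470 for Arp6 KD (replicates 1 and 2). Set 2 was thus sequenced less deeply, and its low genes carry more counting error.

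The values of tables A and B had been scaled separately by the authors. Their recovered reads were therefore put on 1 scale by median-of-ratios factors over all 6 libraries; set 2 kept its deposited values. Features with gene identifiers were tested, and 5578 transposable element features were left out of the gene tests. Of 17869 genes in set 1, 17790 identifiers were found in the reference annotation of BDGP6 and 17769 had the same coordinates, which are the ones printed. The 2 sets were never fitted together.

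The main test was limma (version 3.58.1, R 4.3.3) with an intensity trend on log2(value + 1), for genes with a mean of at least 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The 3 groups of set 1 shared 1 estimate of the spread. The design written before the data were examined foresaw edgeR if the deposited values were counts and limma if they were scaled; the values were scaled, so limma applied. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives chosen after the values were seen. Tables were handled with Python 3.11.15 and pandas 2.3.3.

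Whether libraries with the same number vary together was checked before any calls were compared. In set 1, deviations from the group means correlated between libraries of the same table at 0.62, 0.58 and 0.65 for the 3 pairs of groups (9103 genes with a mean of at least 10). Because all 3 correlations were high and the libraries of each table had been deposited and scaled together, set 1 was read as paired by table. The pairing rests on the shared tables and on these correlations, not on the labels, and set 1 has only 2 tables. Values from the fit with the table as a block stand beside the main ones for the named genes and lists where they change a call. In set 2 the correlation was 0.50 (7976 genes) with only 2 pairs, and the block is given with the alternatives. The labels do not say that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

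Before the data were examined, 22 gene lists were fixed, of which 21 with at least 5 members were tested with camera (limma) at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation. With an estimated correlation camera takes its degrees of freedom from the few libraries, so a list can hardly pass whatever its correlation. A high p from it does not show that correlation among members removes a list result. The preset correlation, in turn, was assumed and not measured. Of 483 list members, 479 were matched to a gene. Named genes followed a rule fixed at the same time. It takes ac, da, Arp6 and His2Av in every comparison, and the 10 largest rises and falls past the threshold without overlap of the groups (or the 10 genes of lowest p if fewer than 3 passed). It further takes up to 4 members of each list with a call or of the proneural and complex lists, and the 5 largest falls of Ac-dependent genes per knockdown. Applying it to the blocked fit was added after the values were seen. Ac-dependent genes were defined as higher under Ac WT than Ac R29G at the threshold with a fold of at least 1.5. No library was without transfected Ac, so whether Ac WT raised these genes or Ac R29G lowered them cannot be told.

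The tests were run on simulated counts drawn from the means and depths of these libraries. The means of each table or replicate were the same for all groups, and the spread came from a blocked fit. A gain from the block was thus built in, so these rates do not test whether the block suits the real libraries. For Ac WT against R29G, limma recovered 42.4% of genes changed 2-fold and 49.2% of those changed 4-fold, and with the block 65.2% and 83.1% (11934 genes), with 4 false calls among 142. For H2A.Z KD it recovered 39.4% and 68.2%, and 66.7% and 81.8% with the block (11909 genes), with 8 false calls among 147. For Arp6 KD it recovered 56.3% and 64.6% (10607 genes). There edgeR with the block made 17 false calls among 159 (8093 genes), or 10.7%.

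Alternatives were other scalings (quantile, median of each library), limma without trend, other low-value filters, a pseudocount of 0.1, a fold minimum of 2, only the 2 groups compared, the replicate block and leaving out each library in turn. The comparisons of Ac WT with R29G and of H2A.Z KD with Luc KD share their Luc KD libraries, so 100 simulated data sets gave the values expected from shared controls. With 2 libraries per group, a split of the controls leaves 1 library per table. Genes with a mean of at least 5 (9941) were therefore also ranked in 1 table and read in the other.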

Results

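RNA was measured in S2 cells that received the proneural factor Ac with its partner Da, in 5 groups of 2 libraries. Set 1 compared Ac WT with Ac R29G under control (Luc) knockdown, and H2A.Z knockdown with Luc knockdown under Ac WT. Set 2 compared Arp6 knockdown with its own Luc knockdown controls, all with Ac WT. The libraries of set 1 fall into table A and table B, as deposited. Libraries held 24500413 to 33712374 reads in set 1 and 9396318 to 10608470 in set 2. Values are size-factor-scaled reads, given as mean ± SD with n = 2 per group unless a library is named. The series title asks whether Arp6 helps proneural proteins to activate genes.

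The targeted gene was lower in each knockdown, to a different degree in each library. His2Av, which encodes H2A.Z (FBgn0001197, BDGP6 3R 26866929 to 26869220, plus strand), fell from 6084 ± 572 to 1246 ± 645 in H2A.Z KD, a log2 change of -2.39 (SE 0.31, adjusted p = 0.0193, limma). The H2A.Z KD libraries held 26.2% (table A) and 13.9% (table B) of the His2Av value in their controls. Arp6 (FBgn0011741, X 15735774 to 15737120, minus strand) was at 483 and 438 in the Luc KD libraries of set 2 and at 386 and 96.5 in the Arp6 KD libraries, which is 79.8% of control in replicate 1 and 22.0% in replicate 2. Its log2 difference of -1.25 (SE 0.51) did not pass limma (adjusted p = 0.701).

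The transfected genes also varied between libraries. Ac RNA (ac, FBgn0000022, X 370031 to 370947) was at 48.5% of control in Arp6 KD replicate 1 and at 92.9% in replicate 2, and da RNA (FBgn0267821, 2L 10388105 to 10393228) at 45.9% and 81.7%; their log2 differences of -0.57 (SE 0.39) and -0.71 (SE 0.32) had adjusted p of 0.740 and 0.702 in limma. In H2A.Z KD, ac was at 81.5% and 105% of control in tables A and B. For da the values were 69.6% and 70.2%, a log2 difference of -0.52 (adjusted p = 0.134 in limma, 1.74e-05 with the table as a block). Between Ac WT and R29G, ac differed by -0.01 (SE 0.29) and da by 0.01 (SE 0.18). The knockdown of Arp6 left His2Av at 3945 ± 307 against 3533 ± 117, a difference of 0.16 (adjusted p = 0.702, limma).

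**Figure D1:**
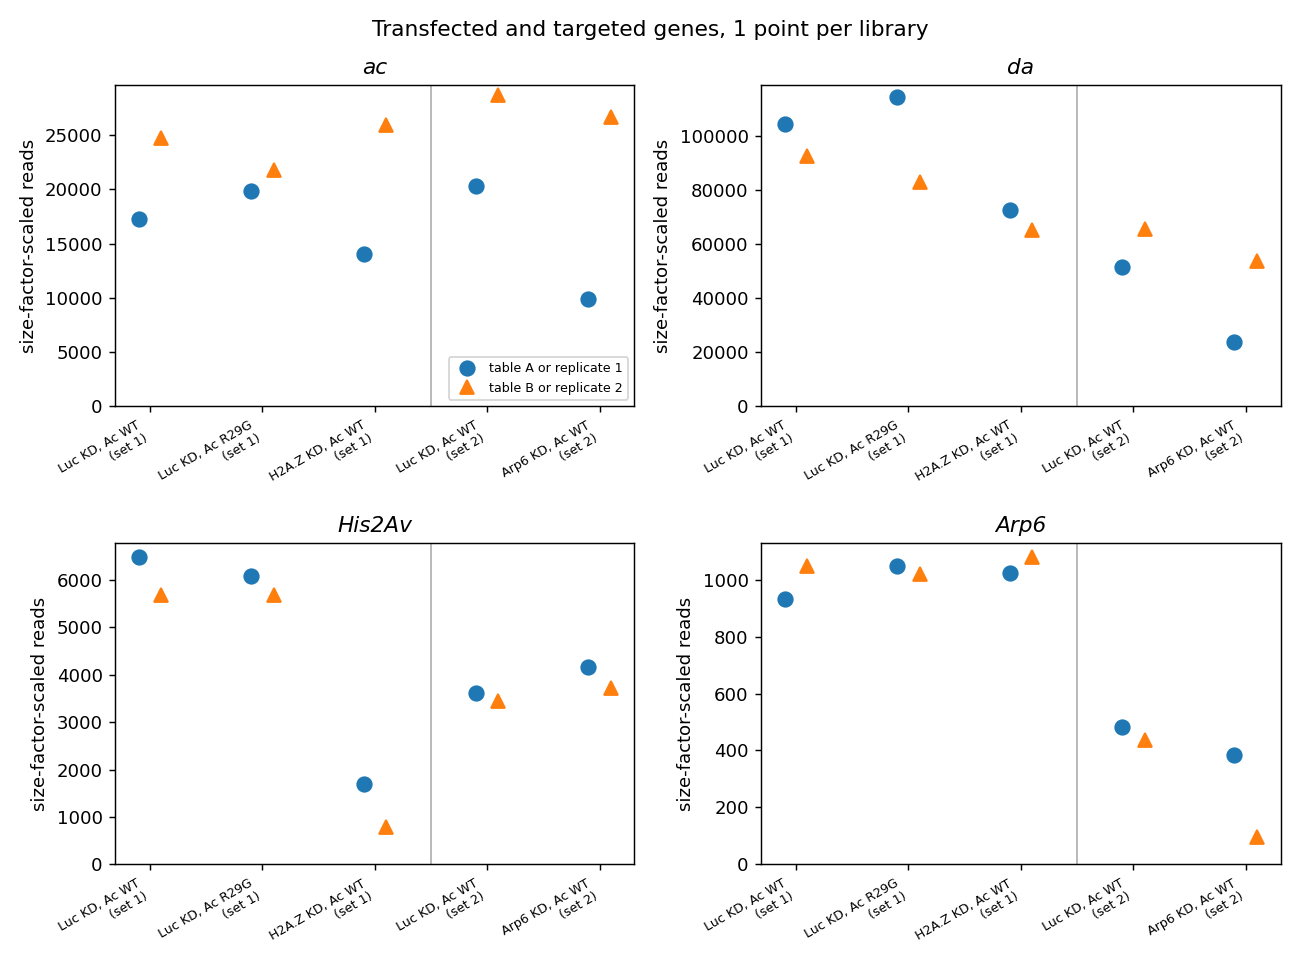
Size-factor-scaled reads (vertical axes, from 0) of ac, da, His2Av and Arp6 in each of the 10 libraries, by group along the horizontal axis; circles are table A or replicate 1 and triangles table B or replicate 2, and the 2 sets are scaled separately. His2Av is at 1702 and 790 in H2A.Z KD, and Arp6 at 386 and 96.5 in Arp6 KD.

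With Ac WT, sca, phyl and mira were higher than with Ac R29G, as tested with the table as a block. The largest difference was in sca, which encodes a secreted glycoprotein that acts in the spacing of sensory precursors (FBgn0003326, 2R 12780541 to 12802010, plus strand), at 1858 ± 2092 against 27.5 ± 8.63, a log2 difference of 5.34. The gene phyl, an adaptor acting in sensory organ precursors (FBgn0013725, 2R 14427336 to 14432337, minus strand), was at 97.3 ± 77.4 against 2.15 ± 3.04, a difference of 5.15. For mira, an adaptor of asymmetric neuroblast division (FBgn0021776, 3R 19931799 to 19935120, minus strand), the libraries held 93.7 and 206 against 39.0 and 43.0, a difference of 1.74. All 3 were higher in both tables, but the level reached with Ac WT differed, with sca at 378 in table A and 3337 in table B.

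Without a block, limma called 0 of 11942 genes (240 at an unadjusted p under 0.05; edgeR called 0 of 9439, with 155 unadjusted, and DESeq2 called 8). With the table as a block, limma called 74 genes, 48 higher and 26 lower with Ac WT, edgeR called 102 higher and 39 lower, and DESeq2 called 39, all among the 74. The block gave sca a difference of 5.34 (SE 0.38, adjusted p = 7.01e-07), phyl 5.15 (SE 0.35, adjusted p = 6.40e-07) and mira 1.74 (SE 0.27, adjusted p = 0.00422). Without 1 library of the compared groups the blocked fit kept fewer of the 74, namely 32 of 52 calls without Luc KD Ac WT table A, 40 of 55 without its table B, 48 of 131 without R29G table A and 42 of 53 without R29G table B. Without H2A.Z KD table A or table B it called 325 and 301 genes, all 74 among them, and limma with the block but without the intensity trend called 0. The authors' deposited table of this comparison held 9 genes past an adjusted p of 0.05, 8 higher with Ac WT, among them phyl (0.00232), CG12111 (0.00232) and sca (0.0319), and RpL39 lower (0.0149).

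The other rises with the block, read from Ac R29G to Ac WT, included NaPi-III (187 ± 177 against 32.4 ± 23.5, log2 2.28), CG5966 (182 ± 176 against 14.2 ± 4.29, 3.17), side-VII (92.6 ± 75.5 against 9.48 ± 3.67, 2.92), CG17919 (69.1 ± 20.6 against 10.6 ± 3.22, 2.59), CG13743 (134 ± 108 against 16.9 ± 1.61, 2.63), RabX5 (17.6 ± 14.1 against 0.861 ± 1.22, 3.25) and CG14312 (15.0 ± 1.91 against 1.33 ± 0.560, 2.80). Smaller differences were seen for CG12111 (212 ± 21.0 against 65.3 ± 19.3, 1.71), sPLA2, a secreted phospholipase A2 by its name (437 ± 80 against 204 ± 25.0, 1.09), and CG34124 (119 ± 5.26 against 47.6 ± 7.62, 1.31). Their adjusted p lay between 3.36e-05 (NaPi-III) and 0.0170 (CG14312) in limma with the block. Lower with Ac WT were the FGF receptor gene htl (28.6 ± 26.0 against 65.2 ± 35.7, -1.40), the calcium channel gene cac (43.7 ± 14.8 against 106 ± 36.0, -1.26), the nidogen gene Ndg (139 ± 40 against 313 ± 83.6, -1.17), btsz (420 ± 125 against 784 ± 108, -0.93) and TotM (788 ± 827 against 1371 ± 1176, -1.04). In the fit without the block TotM, Ac WT vs Ac R29G, had an unadjusted p of 0.389, and its difference was 0.33 without Luc KD Ac WT table A. Further falls were CG10560 (-2.61), CG15529 (-2.03), ogre (-1.35), CCHa2-R (-1.16) and RpL39 (19914 ± 309 against 32342 ± 2594, -0.70). The antisense gene asRNA:CR44083 was at 46.6 ± 3.31 against 117 ± 0.611 (-1.31), but strand is not known, so this cannot be told from its partner. CG42728 (6.64 ± 2.16) and CG31475 (6.73 ± 3.74) had no read with Ac R29G. They passed limma neither without the block nor with it (CG42728 blocked adjusted p = 0.0827).

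Of the lists fixed before the data were examined, the 19 measured sensory organ precursor and proneural target genes lay above the other genes with Ac WT (camera adjusted p = 2.77e-04, and 1.11e-07 with the block; median 0.13, mean 0.87, 14 positive). With an estimated correlation the adjusted p was 0.959. Phyl, sca and mira rose with the block, 2 of the 19 passed adjusted over the list alone without it, and edl, spdo (0.59, blocked adjusted p = 0.145) and others did not pass. In the neuronal list (31 measured) nerfin-1, a zinc finger factor of neuronal differentiation, rose (19.0 ± 20.8 against 2.15 ± 3.04, 2.55, blocked adjusted p = 0.0280) and cac fell, while pros (36.5 ± 4.65 against 13.8 ± 1.15, 1.34, blocked adjusted p = 0.0686) and Sh (1.26, 0.0563) did not pass. None of 12 E(spl) and Bearded genes and none of 13 bHLH genes passed with limma: E(spl)m8-HLH 1.61 (blocked adjusted p = 0.658), E(spl)m6-BFM -1.10 (0.770), Oli 1.12 (0.840).

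Ribosomal protein genes lay lower with Ac WT, with a median of -0.09 over 88 genes (84 lower, camera adjusted p = 9.80e-08; 2.33e-22 with the block, where 6 fell, among them RpL39 and RpL37A at -0.29). Under quantile normalization the median was -0.02 with 59 lower. The adjusted p with an estimated correlation was 0.959. Hemocyte markers had a median of -0.08 (camera adjusted p = 0.429; 0.0152 with the block), and an estimated correlation gave 0.959 as well. Ribosomal protein genes and hemocyte markers lay higher in H2A.Z KD (medians 0.26 and 0.36), whose controls are these same Luc KD Ac WT libraries. Values of the shared libraries could enter both comparisons, which was not tested for the lists. Single members rose with the block in the lists for the SWR1/Tip60 complex (Tip60, an acetyltransferase, 0.39, adjusted p = 0.0228), ecdysone (Hr4, a nuclear receptor, 0.48, 0.0236) and epithelia (shg, E-cadherin, 970 ± 508 against 619 ± 174, 0.57, 0.0158), and in the immunity list TotM fell.

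In H2A.Z knockdown, the phagocytosis receptor gene NimC1 (FBgn0259896, 2L 13973158 to 13976769, minus strand) rose from 342 ± 0.161 to 2049 ± 31.5, a log2 change of 2.58 (SE 0.11, adjusted p = 0.000583). The tetraspanin gene TM4SF (FBgn0020372, 2R 23878197 to 23880860) rose from 6.90 ± 1.09 to 144 ± 34.8 (4.18, SE 0.45), and piwi, a Piwi family gene (FBgn0004872, 2L 10982205 to 10987420), from 43.8 ± 2.95 to 275 ± 110 (2.56, SE 0.31). The Piwi family gene aub fell from 2486 ± 186 to 992 ± 215 (-1.34, SE 0.15) and Dcr-1, which processes microRNA precursors, from 2860 ± 260 to 1743 ± 2.63 (-0.71). Adjusted p in limma were 0.019 for TM4SF, piwi and aub and 0.0213 for Dcr-1.

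In all, limma called 293 genes higher and 262 lower of 11942 in H2A.Z KD (2987 at an unadjusted p under 0.05), and edgeR 334 and 348 of 9439. With the table as a block limma called 2197 higher and 2300 lower, and without the intensity trend it called 2 without the block and 0 with it. The split depended on scaling: the median of each library as scale gave 806 higher and 180 lower (3337 and 1232 with the block) and moved the median over all genes from -0.01 to 0.13, and quantile normalization gave 216 and 196 (1796 and 2017 with the block). Without the block, leaving one library out gave 92 (H2A.Z KD table A), 5 (Luc KD Ac WT table A), 17 (R29G table A), 6 (H2A.Z KD table B), 4 (Luc KD Ac WT table B) or 20 (R29G table B). With the block, leaving one out gave 2699 (Luc KD Ac WT table B) to 4861 (H2A.Z KD table A) calls, with 2631 to 4355 of the 4497 shared. The authors' deposited table held 1465 features past an adjusted p of 0.05, 763 higher and 702 lower.

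The largest rises also included lectin-24Db, CG43886, CG10764 (411 against 52.0, 2.95, SE 0.24), Eglp4, an aquaporin family gene by its name (160 ± 22.4 against 17.9 ± 3.63, 3.10, SE 0.31, adjusted p = 0.0170), CG1208 (2.94), CG18754 (2.83), NT5E-2 (2.80), CG10560 (14.8 against 1.02, 3.14) and lncRNA:CR44948 (3.35). Large falls were CG13313 (2.30 against 37.6, -3.50), Root (7.46 ± 5.37 against 52.4 ± 13.9, -2.80), Scgdelta, a dystrophin complex gene (11.3 against 61.1, -2.43), trk, which encodes the Torso ligand (6.94 against 35.8, -2.26), CG3457 (71.4 against 307, -2.12) and CG30008 (-2.25). Elo68beta (-2.72) has a close paralog and is uncertain. Tomb (7.49 ± 0.953) and Cyp311a1 (5.02 ± 1.33) had no read in H2A.Z KD. CG10560 was also named as a fall with Ac WT against R29G, and both differences rest on the same low Luc KD Ac WT values (mean 1.02).

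All 23 measured hemocyte markers were positive, with a median of 0.36 (camera adjusted p = 1.16e-05); under quantile normalization the median was 0.14 with 6 lower. The adjusted p with an estimated correlation was 0.585. With Ac WT over R29G, which shares the Luc KD libraries, these markers had a median of -0.08, so the 2 results are not independent. NimC1, eater, another phagocytosis receptor gene (3090 ± 104 against 1887 ± 67.2, 0.71) and Sr-CIV (162 against 48.1, 1.73) rose, 4 passed adjusted over the list alone, and 19 rose with the block. Of 31 innate immunity genes, the NF-kappaB factor genes Dif (0.61, adjusted p = 0.0320), dl (0.58, 0.0337) and Rel (0.44, 0.0360) rose, 10 with the block (median 0.50, camera adjusted p = 0.00384; 0.585 with an estimated correlation). Of 23 heat shock and stress genes Hsc70-3, the ER chaperone BiP, rose (146050 against 79656, 0.88), while Hsp68 (0.64) passed only with the block (adjusted p = 0.123, and 2.55e-06 with the block). With the block 12 of the 23 rose and 1 fell (median 0.31, camera adjusted p = 0.00383, and 0.585 with an estimated correlation).

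Cell cycle genes (28 measured) were mostly positive, 23 of them, with a median of 0.20 (camera adjusted p = 6.84e-05; 0.585 with an estimated correlation). CycB (0.51), polo (0.49), tum, a regulator of cytokinesis (0.60), and fzy, the Cdc20 homolog (0.47), rose, and with the block 16 rose and 2 fell. Of 18 SWR1/Tip60 complex members the subunit gene Brd8 (1913 against 2775, -0.54, adjusted p = 0.0371) and His2Av fell and 16 were negative, with a median of -0.22 (-0.06 with median scaling; camera adjusted p = 0.00383, and 0.585 with an estimated correlation). With the block 11 fell and 1 rose, among the falls Tip60 (-0.35, adjusted p = 0.121, and 0.00169 with the block) and YL-1 (-0.36, 0.139 and 0.00218). Without His2Av, the gene knocked down, a check added after the values were seen, the median of the other 17 was -0.21 with 15 negative (camera adjusted p = 0.0133; 0.00301 with the block, where 10 fell; 0.619 with an estimated correlation). In the germline list vas, a helicase gene, rose (225 ± 69.2 against 34.4 ± 7.66, 2.65) and mael (573 against 1191, -1.06) and aub fell, and with the block 1 of 10 rose and 5 fell. Ribosomal protein genes had a median of 0.26 (camera adjusted p = 1.11e-08), but under quantile normalization it was -0.01 with 55 of 88 lower, so its direction depends on scaling; the estimated-correlation adjusted p was 0.668. RpLP2 rose (0.52, adjusted p = 0.0448), and with the block 76 of the 88 rose and 1 fell. The list had a median of -0.09 with Ac WT over R29G, a comparison that shares the Luc KD libraries.

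Genes higher with Ac WT than with Ac R29G were next examined in the knockdown of H2A.Z. Many were lower: side-VII had a log2 difference of -1.64 (adjusted p = 0.188; 0.00816 with the block) and sca of -1.52 (0.476; 0.00427 with the block), while CG17777 (-1.51, 0.0274), CG34124 (-1.24, 0.0465) and zld, the gene of the early embryonic activator Zelda (-1.22, 0.0489), fell by limma. In the fit without the block the difference for sca, H2A.Z KD vs Luc KD, was 0.034 without H2A.Z KD table A and 0.050 without Luc KD table B. Without the block 0 genes met the definition of Ac dependence, also without a minimum fold. With the block 40 did, and 28 of them (70%, against 51.1% of all genes) were lower in H2A.Z KD, 25 in both tables, with 4 called lower, sPLA2 being the fourth, and 0 higher (17 lower and 7 higher with the block). With these 40 genes kept, the number lower was 26 without H2A.Z KD table A, 25 without Luc KD Ac WT table B and 28 without any other library; defined without the block, 0 genes met the definition in each left-out fit. The median was -0.52 (-0.42 under quantile normalization, -0.37 with median scaling; matched random lists -0.15, from -0.31 to 0.05), below the other genes by camera (p = 0.0342), with p = 0.621 with an estimated correlation. Of the 17 genes lower with Ac WT by the same definition, 11 (64.7%) were also lower in H2A.Z KD, with a median of -0.15, inside that of matched random lists (-0.36 to 0.26); 1 was called lower and 2 higher (3 and 6 with the block).

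The comparisons that defined these genes and that tested them share the Luc KD libraries. A split by table leaves 1 library per group, a weak check added after the values were seen. The 100 genes highest in Ac WT over R29G in table A had a median of 0.01 in H2A.Z KD of table B (50 lower; matched random lists -0.11 to 0.24). Those ranked in table B had -0.26 in table A (65 lower; -0.17 to 0.18). The fold changes correlated at -0.32 across genes, while simulated unchanged groups gave -0.48 (-0.51 to -0.44); the covariance was -0.0828 against -0.0635, a difference of -0.0192. Simulated unchanged groups gave a share of lower genes of 92.5% (77.5 to 100), above the observed 70%. In them R29G was unchanged too, so the genes were picked on errors of the shared controls alone. A high share was thereby built in, and it cannot be set against the observed one. With the R29G effects kept, the simulated share was 55.3% (37.5 to 73.0). In the blocked fits, 22 genes were higher with Ac WT and lower in H2A.Z KD (9.24 expected of independent lists) and 11 lower and higher (4.78 expected), and part of this excess may come from the shared controls.

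In the Arp6 knockdown, limma without the block called 3 genes, whose values were close in the 2 replicates. CG14516 (FBgn0039640, 3R 29138662 to 29145787, plus strand) rose from 1203 and 1081 to 2022 and 1854, a log2 change of 0.76 (SE 0.08, adjusted p = 0.0349). CG15695 (FBgn0038832, 3R 20842140 to 20844981) rose from 994 and 957 to 1680 and 1536 (0.72, adjusted p = 0.0349), and CG3335 (FBgn0036018, 3L 9624237 to 9627321) fell from 609 and 636 to 298 and 271 (-1.13, adjusted p = 0.0125). NimC1 was at 203 ± 2.54 against 125 ± 7.42 (0.70, adjusted p = 0.251).

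As genes changed, Arp6 KD vs Luc KD, limma called these 3 of 10605 (739 at an unadjusted p under 0.05) and edgeR called 2 higher and 1 lower of 8087. With the replicate block limma called 0 (1678 at an unadjusted p under 0.05; adjusted p = 0.0502 for each of the 3), but this depended on the filter and the scaling: with the block it called 722 with a mean of at least 5, 181 with median scaling and 22 with quantile normalization, DESeq2 66 and edgeR 870. Without the block limma also called 0 under quantile normalization, without the trend or without a filter on low values. Leaving out Luc KD replicate 1 or replicate 2 gave 0 calls, and leaving out Arp6 KD replicate 1 or replicate 2 gave 5 and 4. CG14516 and CG15695 also rose in H2A.Z KD (1.65, adjusted p = 0.0190, and 1.48, 0.00297), while CG3335 passed there only with the block (-0.36, 0.213, and 0.000827 with the block).

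No member of the fixed lists passed over all genes in Arp6 KD by limma. Ribosomal protein genes had a median of 0.15 with 85 of 86 positive (camera adjusted p = 5.22e-17; 0.632 with an estimated correlation), and 0.03 with 31 lower under quantile normalization. Hemocyte markers (22 of 23 positive, median 0.15, 3.13e-06; 0.632), cell cycle genes (26 of 28, 0.09, 1.79e-05; 0.632) and heat shock genes (16 of 22, 0.19, 3.89e-05; 0.562) lay higher, in the order median, camera adjusted p and adjusted p with an estimated correlation. Under quantile normalization the median of the hemocyte markers was 0.03 with 6 lower. Mitochondrial genome genes lay lower (1 of 12 positive, -0.19, 2.50e-05; 0.562), with a direction kept under both scalings, with mt:ND5 at -0.37 and mt:ND3 at -0.31. Adjusted over the list alone, 6 heat shock genes passed, for example Hsp68 (0.39), and so did NimC1 and dl (0.44); the mitochondrial and heat shock examples and dl were chosen after their values were seen. The SWR1/Tip60 genes dom (0.14, adjusted p = 0.728) and Bap55 (-0.16, 0.708) did not pass, and the list median was near 0 and changed sign with scaling. Heterochromatin genes (12 of 16 positive, median 0.08) and innate immunity genes (19 of 29 positive, median 0.14) lay higher by camera (adjusted p = 0.0229 each; 0.562 with an estimated correlation), and the sensory precursor and proneural targets had a median of 0.03 (17 genes, camera adjusted p = 0.680).

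Of the 40 Ac-dependent genes, 31 were lower in Arp6 KD (77.5%, against 52.9% of all genes), 20 in both replicates and 0 called by limma. The median was -0.22 (-0.17 under quantile normalization with 28 lower, -0.19 with median scaling with 29), below the other genes by camera (p = 0.00701) but with p = 0.648 with an estimated correlation; matched random lists gave -0.06 (-0.14 to 0.03). Of the 17 genes lower with Ac WT, 10 (58.8%) were lower in Arp6 KD, with a median of -0.10 (-0.22 in replicate 1, 0.06 in replicate 2), inside that of matched random lists (-0.29 to 0.14). CG14312 (-1.92), CG12111 (-1.14), CG17777 (-1.06), nerfin-1 (-1.02) and side-VII (-0.64) were lowest, with adjusted p of 0.701 to 0.764 in limma. Sca differed by 0.10, phyl by 0.09 and mira by -0.00, and in replicate 1 alone by -0.00350, -0.18 and -0.25. The replicates differed, with a median of -0.41 in replicate 1 and -0.05 in replicate 2, and the number lower was 38 without Luc KD replicate 1, 9 without Arp6 KD replicate 1, 13 without Luc KD replicate 2 and 39 without Arp6 KD replicate 2.

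**Figure D2:**
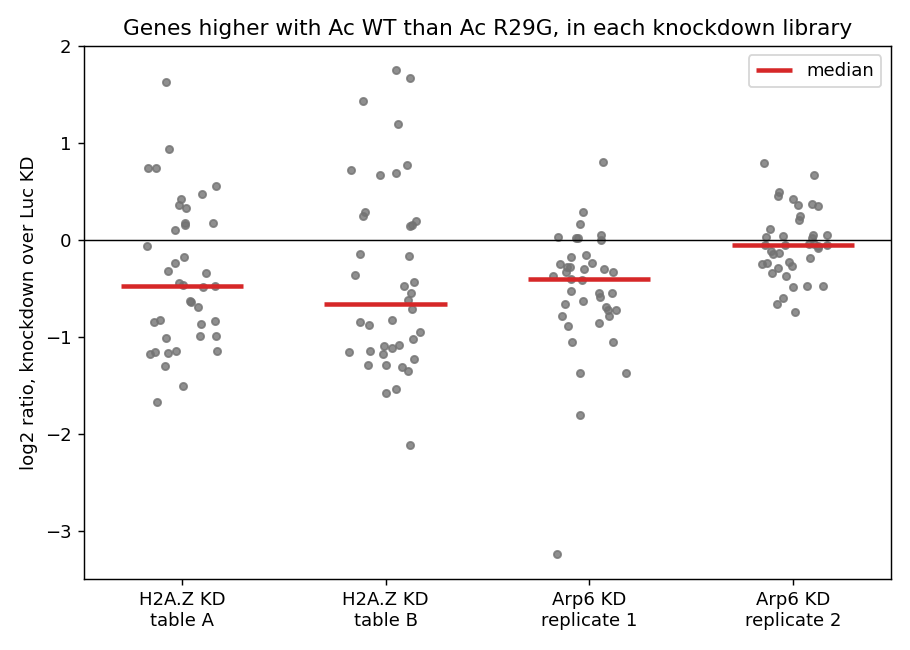
Log2 ratio of each knockdown library to the Luc KD library of the same table or replicate (vertical axis) for the 40 genes higher with Ac WT than R29G in the blocked fit; points are genes, spread sideways for clarity, and bars are medians. Medians are -0.47 and -0.66 in H2A.Z KD and -0.41 and -0.05 in Arp6 KD.

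The 2 knockdowns were compared across genes, which are not independent replicates. Over 10532 genes the log2 fold changes correlated at 0.20 (Pearson) and 0.31 (Spearman), and over 7427 genes with a mean of at least 20 at 0.48 and 0.51. Both genes called higher in Arp6 KD were called higher in H2A.Z KD (2 of 2, 0.0556 expected, Fisher's exact test p = 0.000771), and 0 of 1 called lower was shared.

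**Figure D3:**
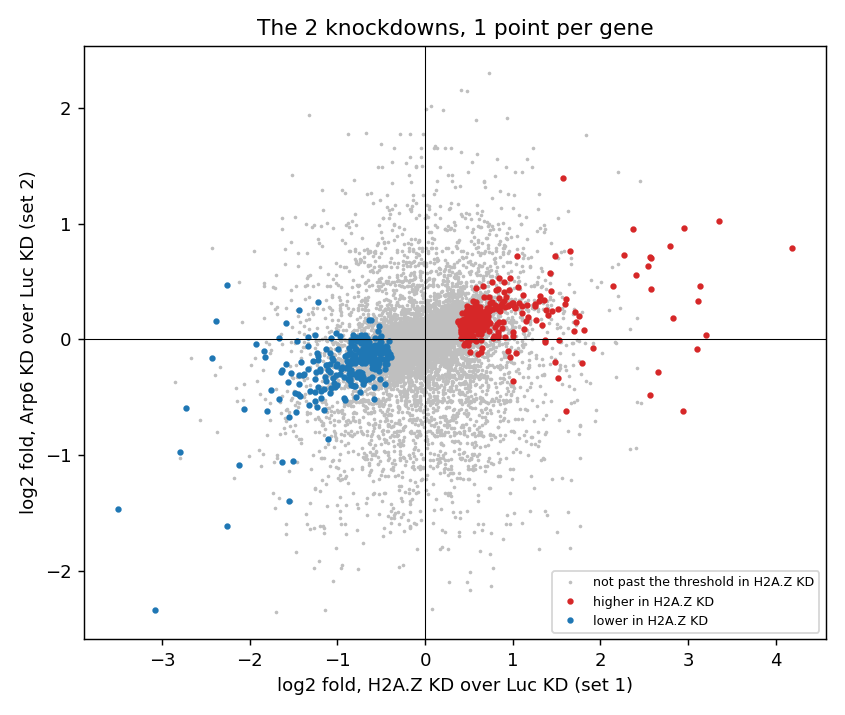
Log2 fold change in H2A.Z KD (horizontal axis) and in Arp6 KD (vertical axis), each over its own Luc KD controls, 1 point per gene over 10532 genes; red and blue points passed the threshold as higher or lower in H2A.Z KD. The correlation over all genes is 0.20 (Pearson).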

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

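The tests of shared controls with the R29G effects kept, of less da RNA, of genes lower with Ac WT and of controls split by table were chosen after the result was seen. So was the reading that the first of these requires both the share and the median to lie in the simulated range, and the reading of the scaling test in the blocked fit.

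Reads on transposable elements, which the gene comparisons left out, took a larger share in H2A.Z KD than in its controls, 0.294% ± 0.00778 against 0.272% ± 0.00461 (SD, n = 2), the lowest knockdown library (0.288%) above the highest control (0.276%). Over 1746 such features limma called 0 (129 at an unadjusted p under 0.05), and 26 higher and 6 lower with the table as a block, with a median log2 difference of 0.17. In Arp6 KD the share was 0.230% against 0.229%.

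The Ac-dependent genes were lower in Arp6 KD in replicate 1 (median -0.41), where ac and da RNA were at 48.5% and 45.9% of control. In replicate 2, where Arp6 RNA was lowest, the median was -0.05 (interval -0.16 to 0.04 over resampled genes). A fall was thus not shown in replicate 2. Stronger loss of Arp6 as the source of the falls predicts the lower median in replicate 2, but the median there was higher by 0.35. That cannot decide against it, because each replicate is 1 pair of libraries and ac and da RNA differed between the replicates too. Less transfected ac and da RNA predicts the lower median in replicate 1, and the difference of -0.35 lay outside that of matched random lists (-0.17 to 0.13). The 17 genes lower with Ac WT, which less ac and da would raise if Ac WT lowers them, did not go the other way. Their difference was -0.27 (interval -0.83 to 0.13 over resampled genes, without library spread), which decides nothing. Lower ac and da RNA stays a candidate explanation on 1 pair of libraries. Sca and phyl, the largest rises with Ac WT, were at only -0.00350 and -0.18 in replicate 1. An additional effect of Arp6 stays open and was not separately tested.

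The Ac-dependent genes of the blocked fit were also lower in H2A.Z KD, 28 of 40 (70%; 26 without H2A.Z KD table A, 25 without Luc KD Ac WT table B, 28 without any other library, and 0 genes defined without the block). Less ac RNA as the source predicts the lower median in table A, where ac was at 81.5% of control. The median there was higher than in table B by 0.19 (interval -0.12 to 0.51 over resampled genes, without library spread). In table B, where ac was at 105% of control, the median was -0.66. This cannot decide it, because each table is 1 pair of libraries whose control also helped to pick the genes. Genes picked in the other table went the other way, at -0.26 in table A and 0.00622 in table B. Chance values of the shared controls stay open. Simulations without any effect gave 77.5 to 100% lower, but their genes were picked on control errors alone, so that range decides nothing. With the R29G effects kept the share was 55.3% (37.5 to 73.0), which includes 70%. The observed median of -0.52 lay outside the simulated -0.10 to 0.05, but this cannot decide against chance either. In these simulations no gene changed in H2A.Z KD, so their medians varied less than those of real genes. Matched random lists of real genes gave -0.31 to 0.05. With the controls split by table the median was below matched random lists in 1 direction (-0.26) but not in the other (0.00622). Less da RNA (at most 70.2% of control in either table) cannot be told apart from an effect of H2A.Z either, since da was lower in both tables. An effect of H2A.Z itself remains a hypothesis.

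The counts of higher and lower genes in H2A.Z KD differed with the scaling. The smaller direction held 18.3% of calls with median scaling, under the 20% set in advance, but 47.6% with quantile normalization, and 27.0% and 47.1% with the table as a block. Median scaling shifts all genes together and so moves the balance by itself, which leaves scaling as the source of the balance open. Bias by gene length is argued against, since 93.3% of the calls of the blocked fit (4174 of 4475 genes with a length) were kept after a length trend was removed. Effects of H2A.Z loss on the called genes remain open as the design's own explanation.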

How the results depend on the processing

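edgeR, DESeq2, the deposited scale, the block joined with another choice, sets kept from the blocked fit, the complex list without the targeted gene, genes lower with Ac WT, controls split by table and the same-direction share were added after the data were seen. For each difference below, the cause was not tested. Depth limits low genes most, in set 2 above all. Where a library is left out, the lone library of the group is assumed to vary like the others.

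In genes changed, Ac WT vs Ac R29G, calls numbered 74 with the replicate block, 141 with edgeR and the block, 8 with DESeq2, 39 with DESeq2 and the block, 63 with quantile normalization and the block, 92 with median scaling and the block, 73 with a mean of at least 5 and the block, and, without 1 library, 0 in each fit without the block (limma; 240 at an unadjusted p under 0.05 with all libraries) and 52 to 325 with it, so 0 to 325 over both.

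In genes changed, H2A.Z KD vs Luc KD, they numbered 986 with median scaling, 2 without trend, 4497 with the replicate block, 152 with a fold of at least 2, 20 with only the 2 groups, 4671 with edgeR and the block, 1391 with DESeq2, 3319 with DESeq2 and the block, 3813 with quantile normalization and the block, 4569 with median scaling and the block, 0 without trend and with the block, 4556 with a mean of at least 5 and the block, 45 with the deposited values as they are, and, without 1 library, 4 to 92 without the block and 2699 to 4861 with it, so 4 to 4861 over both.

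In genes changed, Arp6 KD vs Luc KD, they numbered 0 with quantile normalization, 0 without trend, 0 without a filter, 1 with a pseudocount of 0.1, 1 with a fold of at least 2, 0 with the replicate block (limma; 1678 at an unadjusted p under 0.05; edgeR with the block 870), 16 with DESeq2, 66 with DESeq2 and the block, 22 with quantile normalization and the block, 181 with median scaling and the block, 0 without trend and with the block, 722 with a mean of at least 5 and the block, and 0 to 5 without 1 library. Libraries of set 2 with the same number deviated together at 0.50, with only 2 pairs.

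The gene lists called 0, 0 and 0 with an estimated correlation in the 3 comparisons, and the replicate block gave 3, 6 and 7 list calls. The estimated correlation leaves few degrees of freedom, so those 0 calls were nearly fixed in advance and decide little. Mitochondrial genome genes in Arp6 KD, for example, had an estimated correlation of -0.08, yet the unadjusted camera p went from 4.76e-06 to 0.0404. Ac-dependent genes lower in H2A.Z KD numbered 75 (top 100 by p), 28 (replicate block) and 70 (top 100 of the block), and without 1 library 0 when defined without the block and 25 to 28 with the blocked set kept (0 to 28 over both). In Arp6 KD they numbered 68 of 89, 31 of 40 and 78 of 99 measured genes, and without 1 library 0 and 9 to 39 (0 to 39 over both). Dropping the minimum fold gave 0 in both knockdowns without the block, and 33 and 37 with the replicate block, as an alternative added after the data were seen. The correlation of the 2 knockdowns was 0.36 with a mean of at least 5, 0.17 without a filter, 0.13 with a pseudocount of 0.1, and 0.11 to 0.23 without 1 library. The share of H2A.Z KD calls in the same direction in Arp6 KD, percent, was 77.4% with the replicate block, 92.7% with median scaling and 79.1 to 89.4% without 1 library.

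Some named values changed sign, as log2 differences. For ac, Ac WT vs Ac R29G, the value was 0.037 (quantile) and 0.00686 (median scaling), both also with the block, 0.021 (edgeR), 0.00999 (DESeq2) and -0.29 to 0.27 without 1 library. For da, Ac WT vs Ac R29G, it was -0.00511 (DESeq2) and -0.22 to 0.24 without 1 library. Without 1 library the ranges were -0.15 to 0.016 for Arp6, Ac WT vs Ac R29G, -0.23 to 0.32 for His2Av, Ac WT vs Ac R29G, and -2.42 to 0.33 for TotM, Ac WT vs Ac R29G. For ac, H2A.Z KD vs Luc KD, the value was 0.041 (median scaling, also with the block) and -0.56 to 0.33 without 1 library. The ranges were -3.09 to 0.050 for sca, H2A.Z KD vs Luc KD, and -1.42 to 0.40 for phyl, H2A.Z KD vs Luc KD. In the Arp6 knockdown they were -1.29 to 0.14 for ac, Arp6 KD vs Luc KD, -1.38 to 0.10 for side-VII, Arp6 KD vs Luc KD, -0.67 to 0.87 for sca, Arp6 KD vs Luc KD, and -0.74 to 0.92 for phyl, Arp6 KD vs Luc KD. For mira, Arp6 KD vs Luc KD, the value was 0.094 (quantile) and 0.036 (median scaling), both also with the block, 0.063 (edgeR), 0.062 (edgeR with the block), 0.071 (DESeq2), 0.013 (DESeq2 with the block) and -0.55 to 0.54 without 1 library. Of 1417 named values with a library left out, 30 were reversed, 903 the same, 237 stronger and 247 weaker, and of 2232 under other settings 17, 1688, 313 and 214.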

Other observations

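All results here other than the counts for fixed lists were chosen after the data were seen.

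Genes called in H2A.Z KD mostly moved the same way in Arp6 KD, which has its own controls. Of 293 genes higher in H2A.Z KD, 265 (90.4%, against 47.1% of all genes) were higher in Arp6 KD, with a median of 0.17 (0.18 and 0.16 in the 2 replicates) against 0.01 for matched random lists (-0.003 to 0.03). Of 261 lower genes measured there, 233 were lower, with a median of -0.18. Camera gave p = 3.00e-34 and 4.73e-20, and with an estimated correlation p = 0.110 and 0.0403. The medians were close in the replicates, in which Arp6 RNA was at 79.8% and 22.0% of control. Separate controls do not set an effect common to H2A.Z and Arp6 apart from less da RNA. It was at 69.6% and 70.2% of control in H2A.Z KD and at 45.9% and 81.7% in Arp6 KD.

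In the other lists, calls in H2A.Z KD without the block were at most 1 per list. The sodium pump subunit gene nrv2 (glia list) rose by 0.54 (adjusted p = 0.0478, limma) and MsrA (ecdysone list) fell by 0.72 (0.0404); with the block 3 of 11 glia genes rose and 0 fell, and 2 of 18 ecdysone genes rose and 6 fell. With the table as a block the sensory precursor list held 4 higher and 4 lower genes; cpo was higher (0.86, blocked adjusted p = 1.05e-06), and Dl, a Notch ligand gene, lower (13.6 against 51.5, -1.76, 0.000341), as was nvy (-0.68, 9.15e-05), while edl was higher (0.30, 0.00132). In the heterochromatin list piwi was the only call without the block, and in the RNA interference list (10 measured) it was Dcr-1, in either fit. Blocked calls higher and lower were 4 and 2 of 16 heterochromatin genes, 1 and 1 of 12 E(spl) and Bearded genes, 1 and 2 of 13 bHLH genes, 2 and 11 of 24 Polycomb and Trithorax genes (median -0.13, 0.03 with median scaling), 4 and 0 of 17 EGFR genes, 5 and 2 of 22 apoptosis genes, 5 and 1 of 11 epithelial genes, 3 and 2 of 31 neuronal genes, 2 and 0 of 14 muscle genes and 6 and 1 of 13 mitochondrial genome genes, whose direction flipped under quantile normalization. Apart from piwi, limma without the block called 0 members of the lists just counted (2987 of all genes at an unadjusted p under 0.05).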
